A study of Drosophila melanogaster with 3 samples.

How the data were processed

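Chromatin immunoprecipitation followed by sequencing had been carried out on 3 biological replicates of whole embryos of a transgenic line with GFP-tagged Jarid2, with sonicated fragments of 200 to 800 bp, per the labels. The replicate numbers 1, 2 and 3 were those of the labels. The 10 peak lists used here comprised, for each of the builds dm6 and dm3, a permissive list per replicate, a permissive list of the pooled replicates and an IDR-thresholded list. Per the deposited notes, each permissive list was made from alignments of the replicate, or of the pooled replicates, against a control alignment, and the IDR-thresholded list from the 3 replicate lists and the pooled list. The aligner, the peak caller and their versions were not given in the sources used here.

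In the deposited lists each peak has a signal value, which the authors' caller assigned on a scale of its own for each list, and a −log10 q-value. A separate p-value was not given in the lists. Each permissive list held 30000 peaks, and the IDR-thresholded lists were the 5464 (dm6) and 4746 (dm3) strongest peaks of the pooled lists by signal. The signal was used within a list, to rank and filter peaks and to compare the medians of promoter and distal peaks, and levels were not compared between lists. The −log10 q-value was not used in a test, since 70.8% of the peaks in the IDR-thresholded dm6 list shared its maximum. The permissive lists contain weak regions by design, so equal numbers of strongest peaks (5464, the size of the IDR-thresholded list) were taken from each replicate. Because the IDR-thresholded list was made from the same replicates, their support of its peaks is not independent evidence. Read numbers were not part of the lists, so depth was unknown and its effect on the number of peaks could not be estimated.

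Peak positions are dm6 coordinates counted from 1. Genes, start sites, exons and UTRs were taken from the Ensembl release 115 annotation (BDGP6.54) and sequences from the Release 6 reference assembly, which share coordinates with dm6, and all peaks lay within its chromosome lengths. The dm3 lists were used for counts and for replicate overlap. The chromosomes 2L, 2R, 3L, 3R, 4 and X were used.

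The main tests were fixed before the data were examined. A peak was matched to another when their summits lay within 200 bp. A gene had a promoter peak when a summit lay within 1000 bp of any annotated start site. Chance levels came from 100 circular shifts of the peaks within each chromosome. Each of 20 gene lists was compared with all other protein-coding genes by a two-sided Fisher exact test, and each of 16 motifs at summits with its paired flank by a two-sided exact McNemar test, both with Benjamini-Hochberg adjustment and a threshold of 0.05. In the table of alternatives an unbounded odds ratio was replaced by a fixed ceiling, as for CTCF in 100 bp windows, where the motif occurred in no flank alone. Intervals of odds ratios and shares are exact 95% intervals that cover counting error. Chromosome shares were compared with length shares by two-sided exact binomial tests, and medians of signal by a permutation test with 100000 resamples. Replicate values are the mean ± SD of the replicates' 5464 strongest peaks. The SD measures the spread between these biological replicates, and with 1 group no test between conditions was possible.

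Named genes were chosen by a rule: from each list up to 4 members with the strongest promoter peaks and up to 2 without, by name, the genes nearest to the 20 strongest peaks, and 13 genes of the Polycomb system and its targets. Genes named for another reason are identified as such. The following were set after the files were seen: the limitation to 6 chromosomes, the omission of transposon insertions from the start sites, current symbols for 3 genes (Delta, nanos and caly), the averaging of both directions of each replicate pair, and the spread of locus ratios from replicates. The counts of sites lacking in a replicate and the spacing of summits were also chosen then, as were the distances of summits from start sites, the groups of strongest and weakest peaks, the motif counts at promoter and distal peaks apart, the spans of the Hox complexes and the counts for other kinds of genes. Of the list members, 1 symbol, of a non-coding heat shock gene, was not matched to a protein-coding gene.

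The alternatives tried were other summit and start site distances, other numbers of peaks, the strongest peaks alone, protein-coding starts, a background matched on the number of start sites (10000 random lists, a permutation p), summits anywhere in the gene, each replicate alone, each replicate left out, other locus flanks, other motif flanks and windows, and random windows matched on GC content. Of these, the settings added after the data were seen were the assignment of summits to the nearest start, transposon starts, shifts within the span of the permissive peaks, the omission of 477 peaks with a stronger summit within 300 bp, and the omission of stray genes caught by the name pattern of the cuticle and chorion list (accessory gland genes, Cp110 and Cp190). With a replicate left out, the reproducible peaks held by both others were used. These lists still came from all 3 replicates and held 4100, 4074 and 4180 peaks without replicates 1, 2 and 3. A change with a replicate left out can therefore reflect the stricter list rather than that replicate.

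The list, motif and overlap calculations were tested on simulated data. With peaks planted at 12 of 20 members, 80 of 80 simulated lists were called among 13945 genes, and 1 of 320 lists without planted peaks was called higher. In 2000 simulated windows 4 of 4 planted motifs were called, and 1 of 12 others, BEAF-32, whose sequence shares bases with the planted DRE. The overlap found was 51.0% for a list in which 50.0% of peaks had been kept. Motifs were planted in random sequence, at a larger share of windows than any difference found in the real data. Other simulated peaks lay at random positions and the simulated lists were random genes, so these rates need not hold for the real data. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.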

Results

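Binding of Jarid2, a DNA-binding protein found with Polycomb repressive complex 2 (PRC2), was mapped by ChIP-seq in whole Drosophila melanogaster embryos of both sexes, 0 to 24 h old. The flies carried Jarid2 fused at its C terminus to green fluorescent protein (GFP), and an antibody against GFP was used to pull down the bound chromatin. The series had 1 group of 3 biological replicates, so the comparisons were between replicates, between bound and other regions of the genome, and between gene groups. Each replicate was represented by a permissive list of 30000 peaks on the dm6 genome build. A list of 5464 peaks, thresholded by irreproducible discovery rate (IDR) and here called reproducible, summarised the 3 replicates. It held the strongest peaks of the pooled replicates by signal, so the name does not mean that each peak was found in every replicate. Read counts were not part of the files used here, so the sequencing depth of each replicate was unknown. No sample without GFP was analysed here, so background of the GFP antibody could not be measured.

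The question of how well the replicates located the same sites was addressed with the 5464 strongest peaks of each. Sites at Su(z)2 and Psc, which encode related subunits of Polycomb repressive complex 1 (PRC1), were among the 10 strongest peaks of every replicate, at ranks 1, 2 and 2 for Su(z)2 and 4, 1 and 10 for Psc. Between replicates, 77.2% ± 1.23 (SD over 3 pairs) of the strongest peaks had a partner summit within 200 bp, against 1.59% after the peaks were shifted along their chromosomes. Across the reproducible peaks, the signal of 1 replicate correlated with that of another with a Spearman rho of 0.785 ± 0.0241 (SD over 3 pairs), a description across peaks, which are not independent replicates. All 3 replicates held 3729 of the 5464 reproducible peaks (68.2%), 1167 were held by 2 replicates, 529 by 1, and 39 by 0. Support followed signal: 96.9% of the 2732 strongest reproducible peaks and 39.6% of the 2732 weakest were held by all 3 replicates. A peak counted as held only if it matched 1 of a replicate's 5464 strongest peaks, so weak peaks could fall below that cut. With replicate lists of doubled length, all 3 replicates held 5013 of the 5464 peaks. Neighbouring summits were never closer than 199 bp and 421 pairs lay no more than 220 bp apart, against 81 pairs from there to 400 bp. In all, 477 peaks (8.73%) had a stronger summit within 300 bp, and whether these marked separate sites was not tested.

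Replicate 2 lacked some strong peaks. At 33 reproducible peaks, each within 1000 bp of a start site, replicates 1 and 3 each had a peak among their 2732 strongest and replicate 2 had none within 200 bp among its 30000 peaks. The corresponding numbers were 4 peaks for replicate 1 and 7 for replicate 3. Some of the 33 were second summits of a site already counted, as at Rme-8 and APP-BP1. Another shared its interval with the stronger caps peak, where replicate 2 had a peak of rank 16. With a distance of 1000 bp the count for replicate 2 was 29. The strongest peak absent from replicate 2 lay nearest to CG3552 (chromosome 3L, 9457643 to 9457953), with rank 100 in replicate 1 and rank 12 in replicate 3. The peak at Gapdh2, which encodes a glycolytic enzyme, ranked 377 and 321 in those replicates, and the Abd-B promoter peak 829 and 1014. Within 1000 bp of an Abd-B start, replicate 2 had a peak of rank 4470. These peaks were chosen after their values were seen. The dm3 lists gave 32, 4 and 9 such peaks for replicates 2, 1 and 3.

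Of the 20 strongest reproducible peaks, the first 2 lay at the PRC1 genes Su(z)2 (chromosome 2R, 12996051 to 12997488, signal 3517) and Psc (chromosome 2R, 12980235 to 12981205, signal 3368). They were followed by pk, a planar cell polarity gene (signal 3129), dlp, which encodes a glypican (3021), path, an amino acid transporter gene (3016), and caps, which encodes a cell adhesion protein (2826). The axon guidance genes robo2 (2767) and comm (2738), the metalloprotease gene kuz (2736), the insulin receptor gene InR (2682), and rho (2568), which encodes a protease of EGF receptor signalling, were also in this group. So was bab2, a transcription factor gene on the list of Polycomb targets (2578). The remaining peaks were nearest to CG11050, FER, Ugalt, MYPT-75D, mtgo, Tollo, jvl and Meltrin. Of the 20 summits, 18 lay in an annotated 5' UTR, 18 lay 0 to 100 bp downstream of a start site, and 20 were found in all 3 replicates. The exceptions to the 5' UTR location were CG11050, with the summit in an intron 1055 bp downstream of its start, and Ugalt, with the summit 22 bp upstream and intergenic. The signal is the authors' value for each peak, on a scale of its own for each list.

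To ask which genes carried Jarid2-GFP at their promoters, 20 gene lists were compared with all other protein-coding genes. Of 13945 protein-coding genes, 3556 (25.5%) had a reproducible summit within 1000 bp of a start site, and the share in the replicates was 26.0% ± 1.37 (SD, n = 3). The share was higher in 9 lists, lower in 3, and did not pass the test in 8. Among the lists with a higher share were the Polycomb target genes, mostly developmental transcription factors. This list was fixed by gene name, and Polycomb binding or histone marks at its members were not measured here. Of its 64 members, 58 had a promoter peak (90.6%, replicates 88.5% ± 4.51, SD, n = 3). The odds ratio was 28.7 (95% interval 12.4 to 81.4, two-sided Fisher exact test, Benjamini-Hochberg adjusted p = 7.29e-27). The call was kept in every alternative, but the odds ratio was 13.6 without replicate 2, 17.9 without replicate 3, 14.4 among the 2732 strongest peaks, and 16.6, 47.0 and 17.2 in replicates 1, 2 and 3 alone. Here and below, leaving out a replicate kept only the reproducible peaks held by both others. That list is smaller and was still made from all 3 replicates, so such changes need not be due to the replicate left out. The strongest members of the list were bab2, the homeobox gene ct (rank 109), the limb gene Dll (rank 115) and esg (rank 121), while bab1, byn, Doc2, ind, toe and vnd had no promoter peak. Of these 6, byn, ind, toe and vnd were named because the group was small, after their values were seen.

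Ribosomal protein genes were the other large group with a higher share: 69 of 92 had a promoter peak (75%; replicates 76.8% ± 3.82, SD, n = 3), with an odds ratio of 8.92 (5.48 to 15; Fisher exact test, adjusted p = 2.77e-22). RpS27 (rank 362), RpL7 (rank 415), RpL14 (rank 560) and RpL26 (rank 580) had the strongest peaks, and RpL10 and RpL10Aa had none. Their summits were found 2 bp downstream of the start for RpS27, 31 bp downstream for RpL7, 44 bp upstream for RpL14 and 682 bp upstream for RpL26. The RpL26 summit lay in an annotated 5' UTR of another gene. Housekeeping genes had peaks at 10 of 20 members, among them Gapdh2 (rank 285), alphaTub84B (rank 606), Cyt-c-p and eEF2, and not at Act42A or ATPsynbeta. Their odds ratio was 2.93 (1.09 to 7.84; Fisher exact test, adjusted p = 0.0311). In the same exact test that call was lost without replicate 1 (adjusted p = 0.0798), without replicate 3 (0.0842), with a distance of 2000 bp (0.0852) and with summits anywhere in the gene (0.128). It was also lost against random lists matched on the number of start sites (adjusted permutation p = 0.268).

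Signalling, ecdysone-response, pair-rule, Enhancer of split and gap genes also had promoter peaks more often than other genes. The signalling list had peaks at 16 of 20 members (odds ratio 11.7, adjusted p = 2.03e-06), led by rho, nkd (rank 32), the Frizzled receptor gene fz (rank 37) and the Notch ligand gene Delta (rank 298), and not at arm or ci. Against random lists matched on the number of start sites its odds ratio was 7.41 (adjusted permutation p = 0.0008). Among ecdysone-response genes, 10 of 12 had a peak (odds ratio 14.6, exact test, adjusted p = 0.00015), including the receptor gene EcR (rank 51), Eip78C (rank 107), E23 and Eip75B, and not br or usp. Their odds ratio was 4.91 against the matched random lists (adjusted permutation p = 0.0333), 25.6 among the 2732 strongest peaks, 25.6 with summits anywhere in the gene and 30.7 in replicate 3 alone. Pair-rule genes had peaks at 8 of 9 members (odds ratio 23.4, exact test, adjusted p = 0.000354), with hairy (hry, rank 22), odd, slp1 and opa at the top and ftz without one. Their odds ratio was 13.1 without replicate 2, 12.8 without replicate 3 and 9.40 in replicate 1 alone, and the call was kept. The Enhancer of split complex, a cluster of Notch target genes, had peaks at 8 of 11 members (odds ratio 7.80, exact test, adjusted p = 0.00341). These included E(spl)mbeta-HLH (rank 661), E(spl)m2-BFM, E(spl)m3-HLH and E(spl)malpha-BFM, and not E(spl)m4-BFM or E(spl)m5-HLH, and the odds ratio against the matched random lists was 11.8. Gap genes had peaks at 6 of 8 members (odds ratio 8.78, exact test, adjusted p = 0.00939), with Kr (rank 219), kni, btd and knrl in front and hkb and tll without. In the same exact test the gap gene call was lost without replicate 1 (adjusted p = 0.0959), without replicate 2 (0.102) and in replicate 3 alone (0.315), and the odds ratio was 5.11 among the 2732 strongest peaks. Except for the permutation values, these p-values were from two-sided Fisher exact tests with adjustment over the 20 lists. The tests treated genes as independent, although neighbours such as those of the Enhancer of split complex can share a peak.

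The 3 lists with a lower share were a list of mainly cuticle and chorion genes, chemoreceptor genes, and digestive protease and lysozyme genes. The cuticle and chorion list, defined by a name pattern, had promoter peaks at 2 of 140 members (odds ratio 0.0418, 0.00501 to 0.154; Fisher exact test, adjusted p = 1.35e-14). The 2 were Cpr73D (rank 1103) and Cp190 (rank 909). The cuticle gene Acp1 and the accessory gland gene Acp24A4 were among those without. The pattern had also caught 17 accessory gland genes (0 with a peak), the insulator protein gene Cp190 and the centriole gene Cp110. Without these, 1 of 121 members had a peak (odds ratio 0.0240, 0.000603 to 0.137; Fisher exact test, adjusted p = 1.06e-13), an alternative chosen after the data were seen. The odds ratio was 0.0273 without replicate 1, 0.026 without replicate 3, 0.0219 in replicate 2 alone, 0.0732 among the 2732 strongest peaks, 0.106 within 2000 bp and 0.0675 with summits anywhere in the gene, and the call was kept. Chemoreceptor genes had peaks at 5 of 179 members (odds ratio 0.0827, 0.0265 to 0.197; Fisher exact test, adjusted p = 8.13e-16). The 4 strongest, at Or71a, Ir48c, Gr64a and Or88a, had summits 980, 904, 842 and 632 bp from the chemoreceptor start. The odds ratio was 0 within 500 bp, 0.155 within 2000 bp, 0.136 with summits anywhere in the gene and 0.045 in replicate 1 alone, and the call was kept. When each summit was given only to its nearest start site, 0 chemoreceptor genes and 0 genes of the cuticle and chorion list had a peak. Digestive protease and lysozyme genes had peaks at 2 of 33 members, Jon65Ai and LysB (odds ratio 0.188, Fisher exact test, adjusted p = 0.0148). The LysB peak (rank 5282) was held by 0 replicates among their 5464 strongest peaks, and the replicates had 1, 1 and 0 members with a peak. That call was lost against the matched random lists (odds ratio 0.283, adjusted permutation p = 0.146). The odds ratio was 0 without replicate 1, without replicate 2, in replicate 3 alone, within 500 bp and among the 2732 strongest peaks. It was 0.114 without replicate 3, 0.0836 and 0.0959 in replicates 1 and 2 alone, and 0.122 with the nearest start.

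**Figure D1:**
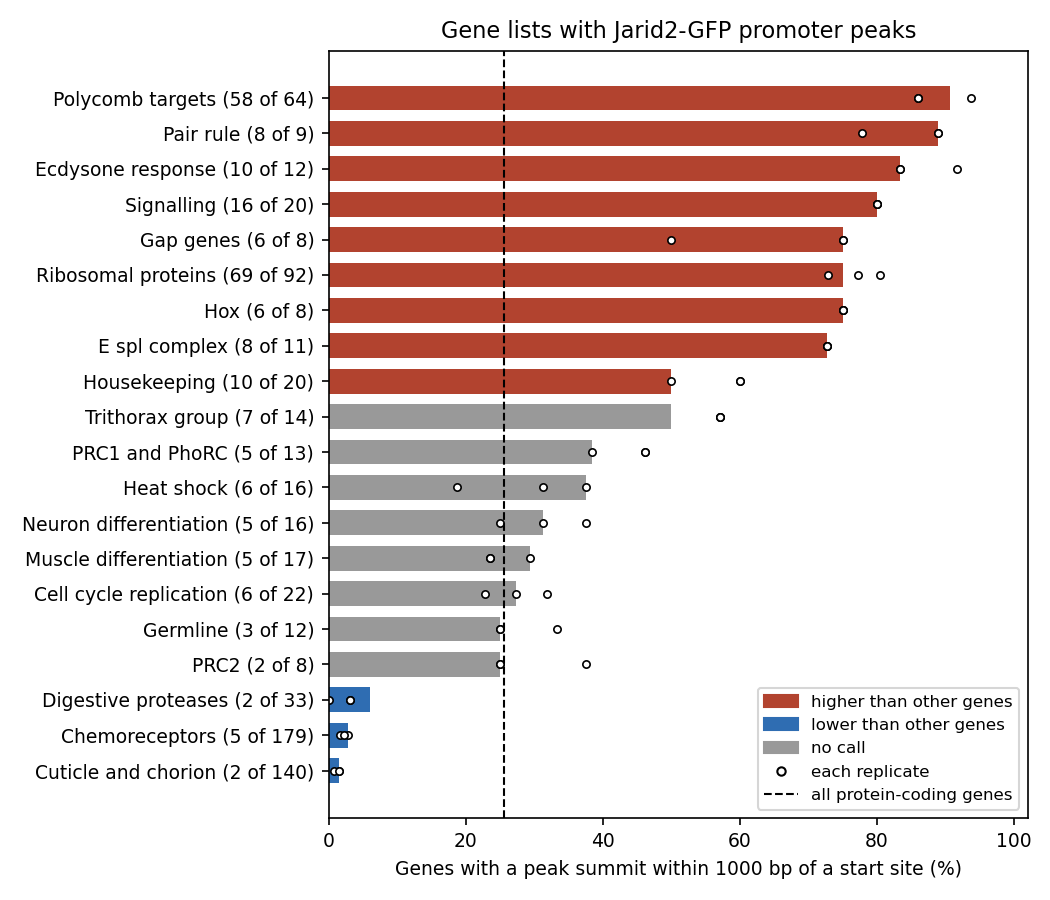
Share of protein-coding genes of each list with a Jarid2-GFP peak summit within 1000 bp of a start site (percent, horizontal axis), for 20 lists. Bars show the list of reproducible peaks, open circles the 3 replicates' strongest 5464 peaks, the dashed line all protein-coding genes (25.5%), and colours the outcome of the Fisher exact test after adjustment; Polycomb targets stand highest at 90.6% and the cuticle and chorion list lowest at 1.43%.

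Genes that encode Polycomb and Trithorax proteins were tested as 3 further lists. Of the PRC2 list, 2 of 8 genes had a promoter peak: jing, which encodes a zinc-finger cofactor (rank 174), and E(z), the histone methyltransferase (rank 1272). Their odds ratio was 0.974 (0.0961 to 5.45; Fisher exact test, adjusted p = 1) and turned direction in several alternatives, for example to 1.70 among the 2732 strongest peaks. The genes of esc, Su(z)12 and Caf1-55 had no reproducible promoter peak. Nor did Jarid2 itself, where replicate 3 had a peak of rank 1483 at the promoter and replicates 1 and 2 had none among their 30000 peaks. The list of PRC1 and PhoRC genes, which also held Asx and caly of another Polycomb complex, had peaks at 5 of 13 members (odds ratio 1.83, exact test, adjusted p = 0.45). The members with a peak were Su(z)2, Psc, Kdm2 (rank 376), ph-p (rank 442) and ph-d (rank 473), and not Pc or Asx. Of these, ph-d was named because the group was small, after its value was seen. Among the 2732 strongest peaks the odds ratio of this list was 3.20 (exact test, adjusted p = 0.0734). Trithorax group genes had peaks at 7 of 14 members, with brm (rank 910), Trl (rank 1079), kis and trx in front and Snr1 and Utx without. Their odds ratio was 2.93 (0.875 to 9.78; Fisher exact test, adjusted p = 0.0899), which did not pass the threshold. It passed in the exact test of each replicate alone (adjusted p = 0.0447, 0.0152 and 0.0244), when replicate 1, 2 or 3 was left out (0.0251, 0.0257 and 0.0283), within 500 bp (0.037) and among the 2732 strongest peaks (0.0318). It did not pass within 2000 bp (odds ratio 2.40, exact test, adjusted p = 0.211), with summits anywhere in the gene (0.0642), with the nearest start (0.0737) or without peaks near a stronger peak (0.0898). Against random lists matched on the number of start sites the odds ratio was 1.71 (adjusted permutation p = 0.514).

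Of the remaining lists, 5 did not pass the Fisher exact test. Heat shock genes had peaks at 6 of 16 members (exact test, adjusted p = 0.373), with Hsp27 (rank 417), Hsp83 (rank 711), Hsp26 and Hsp22 named and Hsf and Hsp23 without. The Hsp22 peak (rank 3547) was held by 1 replicate. It also counted for Hsp67Bc and CG4456, which are named here because they share it. Cell cycle and replication genes had peaks at 6 of 22 (exact test, adjusted p = 0.899), including Dp, E2f1, CycB3 and Mcm5, and not Cdk1 or Cdk2. Muscle genes had peaks at 5 of 17 (exact test, adjusted p = 0.899), including the transcription factor gene Mef2 (rank 1166), Actn, Tm1 and sls, and not Act87E or Mf. Neuronal genes had peaks at 5 of 16 (exact test, adjusted p = 0.716), including Syx1A (rank 481), elav (rank 612), brp and nrv3, and not Appl or ChAT. Germline genes had peaks at 3 of 12 (exact test, adjusted p = 1), namely orb, gcl and tud, and not AGO3 or aub. The gcl summit lay 507 bp upstream, in an annotated 5' UTR of another gene. With each summit given only to its nearest start, 1 of 12 germline genes had a peak.

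The Hox genes, classical targets of Polycomb repression, were examined at promoters and across their complexes. Promoter peaks were found at 6 of 8 Hox genes (odds ratio 8.78, 1.57 to 88.9; Fisher exact test, adjusted p = 0.00939), the strongest at lab (rank 447), Abd-B (rank 1015), Ubx (rank 1753) and Scr (rank 3285). Antp followed at rank 3390, and abd-A and pb had none. The Hox call was lost against random lists matched on the number of start sites (adjusted permutation p = 0.129) and among the 2732 strongest peaks (exact test, adjusted p = 0.185). The bithorax complex (chromosome 3R, 16656623 to 16972236) held 12 peaks, of which 10 lay more than 1000 bp from a start site and 5 were found in all 3 replicates. The Antennapedia complex (chromosome 3R, 6661427 to 6999228) held 22 peaks, of which 11 were distal and 11 were found in all 3 replicates. Within 10000 bp of the Hox genes lay 26 peaks, against 20.5 ± 8.34 (SD over 100 shifts, maximum 41) for shifted peaks, a ratio of 1.27 that was within the spread of the shifts and turned to 0.741 among the 2732 strongest peaks and 0.993 with a flank of 0 bp. The same count for the Polycomb target genes was 190, against 96.6 ± 17.0 (maximum 153), and exceeded all 100 shifts. The ratio was 1.97 (replicates 1.90 ± 0.249, SD, n = 3), and 1.77 with shifts within the span of the permissive peaks. Shifted peaks lose the preference for start sites, and loci of other genes were not compared. The ratio therefore does not separate the promoter peaks of these genes from further peaks across their loci. At the Polycomb targets en and inv, neighbouring homeobox genes, the promoter peaks had ranks 3412 and 821.

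**Figure D2:**
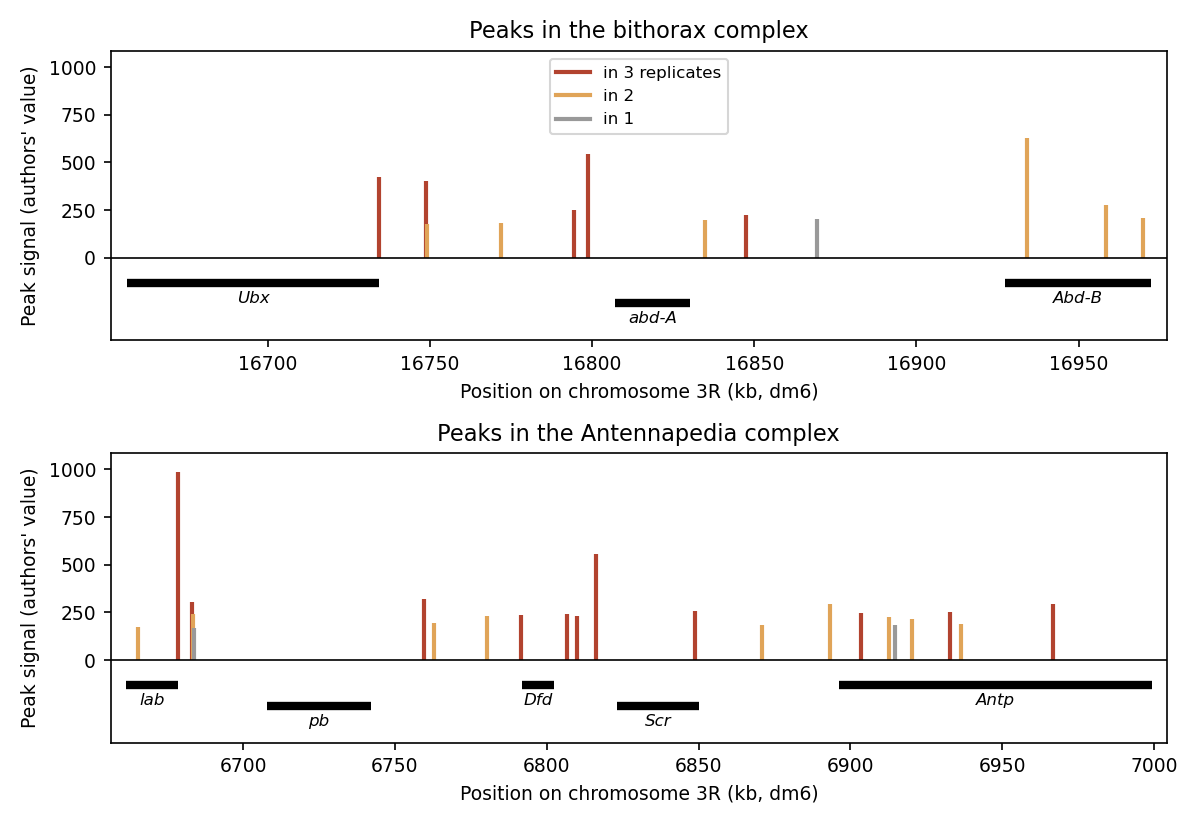
Reproducible Jarid2-GFP peaks along the bithorax complex (upper panel, 12 peaks) and the Antennapedia complex (lower panel, 22 peaks) of chromosome 3R. Vertical lines stand at peak summits with the authors' signal value as height, coloured by the number of replicates that held the peak; black bars are Hox gene spans and positions are in kb on dm6.

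The reproducible peaks were concentrated at the 5' ends of genes. Of the 5464 peaks, 72.9% had a summit within 1000 bp of an annotated start site (replicates 73.1% ± 1.55, SD, n = 3), against 23.8% ± 0.923 (SD over 100 shifts, maximum 25.9%) after shifting. Outside promoters, 17.6% of summits were intronic, 8.24% intergenic and 1.30% exonic. Summits fell in a 5' UTR in 42.6% of peaks (shifted 3.38%) and in a 3' UTR in 0.86% (shifted 5.70%). Among 3786 peaks within 1000 bp of a protein-coding start, the median summit lay 49 bp downstream (quartiles -49 and 80 bp; replicates 48.3 ± 2.08 bp, SD, n = 3). Of these summits, 51.2% lay 0 to 100 bp downstream and 9.90% within 100 bp upstream. The position depended on signal. Among the 1093 strongest peaks, 74.5% of such summits lay 0 to 100 bp downstream (quartiles 30.25 and 69 bp). The share was 34.4% among the 1092 weakest (quartiles -114.5 and 115.75 bp). A smaller group of 196 summits lay 220 to 320 bp downstream, and 84.2% of them had a stronger summit within 300 bp.

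**Figure D3:**
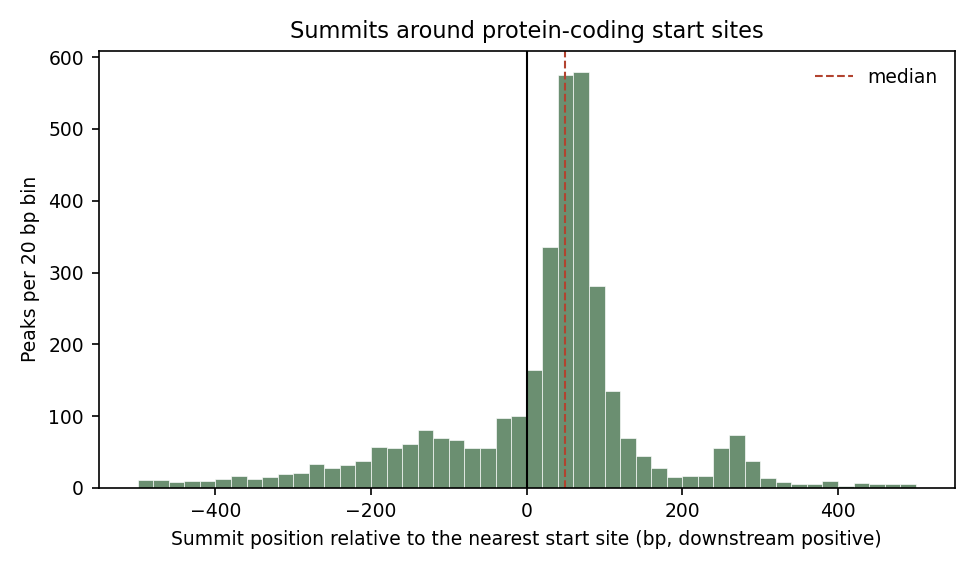
Number of reproducible peak summits per 20 bp bin (vertical axis) by distance to the nearest protein-coding start site in bp (horizontal axis, downstream positive). The dashed line marks the median of 49 bp downstream, and 51.2% of the 3786 summits within 1000 bp lay 0 to 100 bp downstream.

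Promoter peaks were stronger than distal peaks. The median signal of 3981 promoter peaks was 335.8 and that of 1483 distal peaks 233.9, a ratio of 1.44 (two-sided permutation test of medians, p = 1e-05, the smallest that 100000 resamples can give). The same direction was found with the signal of each of the 3 replicates, with ratios of 1.56, 1.49 and 1.39. The promoter share was 92.6% among the 1093 strongest peaks and 56.9% among the 1092 weakest. The peaks of the 2 groups were found in all 3 replicates in 99.2% and 9.16% of cases. Peaks are not independent replicates, so the test describes this list.

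Sequence motifs of promoters and of Polycomb-associated DNA-binding proteins were counted in 200 bp windows at the summits and in windows centred 1000 bp to the left. Most summits lay near start sites, so summit windows often held a core promoter that the flank did not. Promoters without a peak were not compared, so these counts do not separate features of Jarid2-GFP sites from those of promoters in general. The core promoter Initiator (TCAGTY) was found at 29.8% of summits and 16.9% of flanks (odds ratio 2.09, 1.90 to 2.30; exact McNemar test, adjusted p = 7.17e-56). The motif of Zeste was found at 39.6% and 27.2% (odds ratio 1.74, exact test, adjusted p = 3.95e-41), and the GAGAG element bound by GAGA factor at 31.3% and 22.6% (odds ratio 1.56, adjusted p = 1.67e-23). Motifs of housekeeping promoters were more frequent at summits at low frequency, with the M1BP motif at 2.25% and 0.476% (odds ratio 5.04, exact test, adjusted p = 3.57e-16) and the DNA replication-related element (DRE) at 1.48% and 0.531% (odds ratio 2.79, adjusted p = 1.67e-06). The odds ratio of M1BP was 2.64 in 100 bp windows and that of DRE 1.84 with flanks 500 bp away, and both calls were kept. The BEAF-32 motif (odds ratio 1.77, exact test, adjusted p = 7.69e-11), GT repeats bound by Combgap (1.69, adjusted p = 3.88e-10) and the longer GAGA repeat (1.57, adjusted p = 0.000409) were also more frequent at summits. With flanks 500 bp away, GT repeats (exact test, adjusted p = 0.167) and the longer GAGA repeat (0.789) lost the call, and in 100 bp windows the longer GAGA repeat did (0.185). Against GC-matched random windows its odds ratio was 3.25. The motif of Pho, a sequence-specific Polycomb protein, was found at 6.99% of summits and 7.96% of flanks (odds ratio 0.869, 0.751 to 1.00; exact test, adjusted p = 0.0849), and passed the exact test as less frequent with flanks 1000 bp to the right (adjusted p = 0.0349) and against GC-matched random windows (0.0125). The motif of Spps and related KLF proteins was less frequent at summits (17.5% against 19.5%, odds ratio 0.871, exact test, adjusted p = 0.0105). That call was lost in exact tests with flanks 500 bp away (adjusted p = 0.409), in 100 bp windows (0.153), against GC-matched random windows (0.0501) and among the 2732 strongest peaks (0.0776). Motifs of Zelda, CTCF and Su(Hw), the E-box CAGCTG and A tracts did not pass the exact test (adjusted p = 0.298, 0.252, 0.259, 1 and 0.787). Of these, Zelda against GC-matched windows (exact test, adjusted p = 0.0488), CTCF in 100 bp windows (0.0312) and A tracts with flanks 500 bp away (0.0269) passed it.

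Motifs were also counted at promoter and distal peaks apart, without a test of the difference between them. Among 1483 distal peaks, GAGAG (29.9% against 22.8%, odds ratio 1.45, adjusted p = 0.00011) and the TATA box TATAAA (30.3% against 23.3%, odds ratio 1.45, adjusted p = 0.00011) passed the exact McNemar test, and the other 14 motifs did not. At promoter peaks GAGAG was found at 31.8% of summits and 22.6% of flanks (odds ratio 1.60, exact test, adjusted p = 1.82e-19) and the TATA box at 21.5% and 21.4% (odds ratio 1.00, adjusted p = 1). The Initiator was found at 33.8% of promoter summits and 16.4% of their flanks (exact test, adjusted p = 2.46e-70), and at 19.3% of distal summits and 18.3% of their flanks (exact test, adjusted p = 0.667). Over all 5464 peaks the TATA box reached an odds ratio of 1.12 (exact test, adjusted p = 0.0266), which was lost without replicate 1 (adjusted p = 0.188), without replicate 3 (0.475), with flanks 1000 bp to the right (0.0695) and in 100 bp windows (0.731). Its direction turned with flanks 500 bp away (odds ratio 0.937) and among the 2732 strongest peaks (0.987). Mean GC content was 42.9% at summits and 42.1% at flanks.

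**Figure D4:**
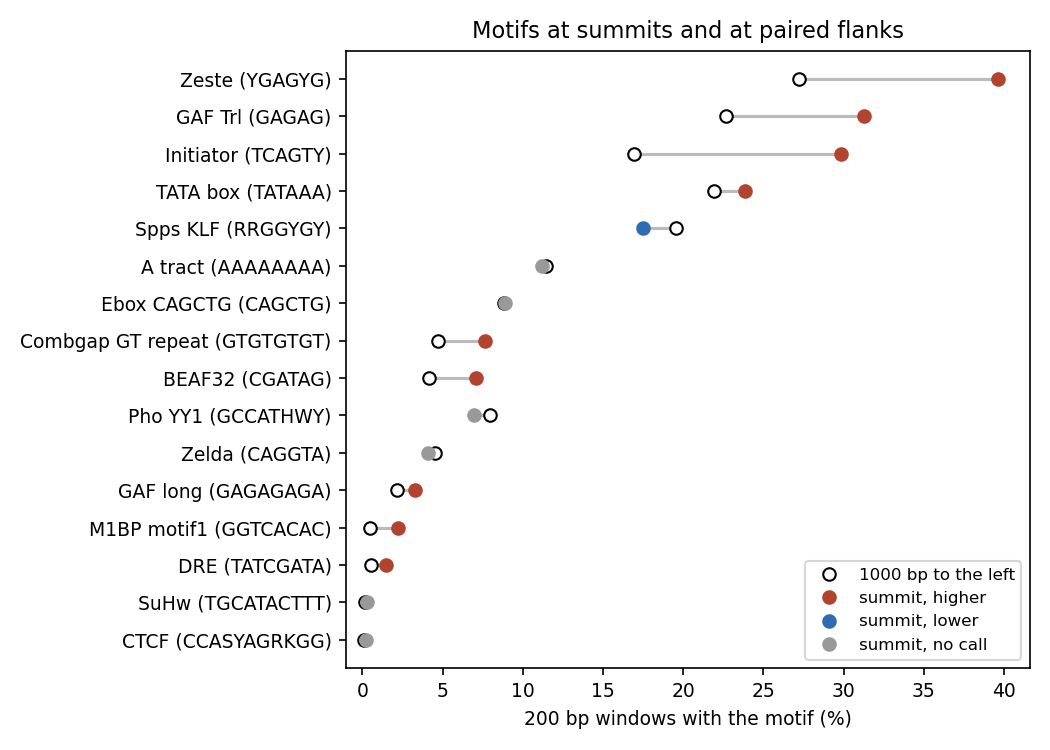
Share of 200 bp windows with each of 16 motifs (percent, horizontal axis) at the summits of 5464 reproducible peaks (filled circles) and 1000 bp to their left (open circles). Colours give the outcome of the exact McNemar test after adjustment; the Initiator moves from 16.9% at flanks to 29.8% at summits.

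Chromosome 4 and the X chromosome held fewer peaks than their lengths would give. Chromosome 4, which is small and largely heterochromatic, held 20 peaks, 0.363 of the number expected by length (two-sided exact binomial test, p = 9.79e-08), or 14.8 peaks per Mb. The X chromosome held 847 peaks, 0.882 of the expected number (exact binomial test, p = 4.35e-05), or 36.0 per Mb. The autosomal arms 2L, 2R, 3L and 3R held 44.7, 43.8, 41.9 and 39.2 peaks per Mb. Their ratios to the expected number were 1.095 (exact binomial test, p = 0.00129), 1.07 (p = 0.00906), 1.03 (p = 0.295) and 0.962 (p = 0.113), in tests that were not planned and without adjustment. Of 80 protein-coding genes on chromosome 4, 7.5% had a promoter peak, against 23.5% on the X chromosome and 24.9% to 27.0% on the autosomal arms. Chromosome lengths include heterochromatin, and neighbouring peaks are not independent. The embryos were of both sexes, so the X chromosome and the autosomes differed in copy number, which these tests did not take into account.

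The authors deposited peak lists on 2 builds of the genome. The reproducible list held 5464 peaks on dm6 and 4746 on dm3, a ratio of 1.15. The X chromosome held 15.5% of the dm6 peaks and 15.7% of the dm3 peaks, and chromosome 4 held 20 and 19 peaks. No coordinates were converted between builds.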

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

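The settings chosen after the data were seen were nearest-start assignment, transposon starts, shifts within the span of permissive peaks, the omission of peaks with a stronger summit within 300 bp, and the omission of stray members of the cuticle list. The cause of the changes given here was not tested unless stated. The number of gene lists with a higher share ranged from 7 to 10 and with a lower share from 2 to 3 over all alternatives, and that of motifs more frequent at summits from 6 to 9. Peaks found in every replicate used ranged from 3390 to 5013 on dm6, with 3258 of 4746 on dm3, and the ratio of promoter to distal signal from 1.39 to 1.56. The observed over expected peaks of the X chromosome ranged from 0.864 to 0.90 and of chromosome 4 from 0.291 to 0.40, and each kept its side of the threshold. Replicate overlap was 71.7% with summits within 100 bp, 79.7% with peaks sharing 1 bp, 85.7% for the top 1000 peaks, 65.9% for doubled lists, and 75.7% to 77.9% with a replicate left out. Rank correlation was 0.811 within 100 bp, 0.816 among the 2732 strongest peaks, and 0.757 to 0.80 with a replicate left out. The promoter share was 66.3% within 500 bp, 80.9% within 2000 bp, 83.5% among the 2732 strongest peaks, 69.3% for protein-coding starts, and 76.0% to 77.7% with a replicate left out. Widening the distance can by construction only raise it. The promoter share over shifted peaks was 2.75 with shifts within the span of permissive peaks. The ratio of peaks around Hox genes to shifted peaks was 0.993 with a flank of 0 bp, 0.741 among the 2732 strongest peaks, 1.41 without peaks near a stronger peak, and 1.03 to 1.39 with a replicate left out. That around Polycomb targets was 1.64 among the 2732 strongest peaks and 1.65 to 1.90 with a replicate left out. Motifs less frequent at summits numbered 2 with flanks to the right, 0 in 100 bp windows, 2 against GC-matched random windows and 0 among the 2732 strongest peaks.

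Values that changed direction were mostly those of lists and motifs without a call. The odds ratio of the PRC2 list was 1.12 within 500 bp, 1.70 among the 2732 strongest peaks, 1.03 in replicate 2, 1.67 in replicate 3, 1.30 with the nearest start, and 1.22 to 1.28 with a replicate left out. Heat shock genes had 0.710 in replicate 2 and 0.845 to 1.70 with a replicate left out. Cell cycle genes had 0.510 among the 2732 strongest peaks, 0.895 with the matched background, 0.905 in replicate 2, 0.615 with the nearest start, and 0.591 to 0.814 with a replicate left out. Muscle genes had 0.998 within 2000 bp, 0.499 with the matched background, 0.947 in replicate 2 and 0.855 in replicate 3. Neuronal genes had 0.730 among the 2732 strongest peaks, 0.615 with the matched background, 0.927 in replicate 3, and 0.845 to 1.25 with a replicate left out. Germline genes had 1.16 with summits anywhere in the gene, 1.34 in replicate 1, 1.03 in replicate 2, and 0.749 to 1.22 with a replicate left out. The E-box had 0.924 with flanks 500 bp away, 0.913 in 100 bp windows, 0.930 among the 2732 strongest peaks, 0.995 without peaks near a stronger peak, and 0.924 to 0.963 with a replicate left out. A tracts had 1.04 with flanks to the right, 1.1 against random windows, and 0.990 to 1.05 with a replicate left out. The TATA box, which had a call, had 0.937 with flanks 500 bp away and 0.987 among the 2732 strongest peaks. No density by chromosome was computed on dm3, for which no lengths were used here. No paired analysis was possible because there was 1 group. Depth was unknown, so how far it limits the number of weak peaks could not be estimated.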

Other observations

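The test of tRNA genes was chosen after its result was seen, and the patterns weighed here were themselves found in the data. Other kinds of genes were counted without a test against protein-coding genes. Of 290 tRNA genes, transcribed by RNA polymerase III, 21 had a reproducible summit within 1000 bp (7.24%, exact 95% interval 4.54 to 10.9%), and 3 had one within 200 bp. Of 269 snoRNA genes 20.4% had a summit within 1000 bp and 3.72% within 200 bp, and of 3261 non-coding RNA genes 13.6% and 4.23%. Small nuclear RNA genes had a summit within 1000 bp at 18.8% of 32 genes (exact 95% interval 7.21 to 36.4%), and within 200 bp at 5, against 25.5% and 19.9% of protein-coding genes. Of 99 ribosomal RNA genes 0 had a summit within 1000 bp, and of 5809 transposon insertions 2.79%. How well reads map to such repeated sequences was not known from the peak lists, so low shares need not mean low signal.

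Strong peaks that a single replicate held were counted as well, a count chosen after the data were seen. Of its 2732 strongest peaks, replicate 3 had 28 with no peak within 200 bp in either other replicate, replicate 1 had 10 and replicate 2 had 5. With a distance of 1000 bp the counts were 20, 5 and 1. At this distance 29 strong peaks of replicates 1 and 3 were absent from replicate 2, and 0 strong peaks of both others were absent from replicate 1 or from replicate 3.

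The position of summits downstream of the start site was the first pattern weighed. A fixed offset of the peak calls in genome coordinates would give medians of opposite sign on the 2 strands, but they were 45 and 52 bp downstream for the 2 strands. Choice among several annotated starts was argued against by the 1611 peaks at genes with 1 annotated start, where the median was 50 bp. The pause button sequence KCGRWCG, associated with paused RNA polymerase II, was counted in the 100 bp downstream of the start. It was found more often for promoter peaks with the summit 0 to 100 bp downstream than for other promoter peaks. The shares were 24.9% and 18.0% (odds ratio 1.51, 1.29 to 1.77, Fisher exact test across peaks, p = 2.66e-07). One hypothesis is that the signal follows the position of paused polymerase or its nearby chromatin, but wrongly annotated starts could also give fewer such sequences. A start with 2 summits could enter both groups, so the peaks are not independent. The groups also differed in signal. Summits lay 0 to 100 bp downstream for 74.5% of promoter peaks among the 1093 strongest peaks and 34.4% among the 1092 weakest. The test did not take signal into account, so the hypothesis stays open.

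The peaks at ribosomal protein genes were the second pattern. Signal at strongly transcribed genes of any polymerase would give tRNA genes at least the share of protein-coding genes. A summit was found at 7.24% of tRNA genes, with an upper limit below the 25.5% of protein-coding genes, while the interval of small nuclear RNA genes includes 25.5%. The peak lists do not show how well reads map to multi-copy genes such as tRNA genes, and protein-coding genes can have several start sites. The low tRNA share is therefore only weak evidence against this explanation, and strong transcription by RNA polymerase II stays open. Peaks of neighbouring genes were argued against by the odds ratio with each summit given to its nearest start, which was 8.21 (5.22 to 13.2). A promoter rich in GAGA elements, as at the Polycomb targets, was argued against by the share of bound promoters with GAGAG, which was 14.5% (7.17 to 25%) at 69 ribosomal protein genes and 62.1% (48.4 to 74.5%) at 58 Polycomb targets. The hypothesis that Jarid2-GFP may reach these 2 groups of promoters in different ways is left open beside non-specific signal of the GFP antibody at accessible promoters, for which no control was analysed here.

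The higher promoter share of strong peaks was the third pattern. If weak distal peaks were merely irreproducible, the share should level out among the 3729 peaks found in all 3 replicates. There it was 87.0% in the stronger and 69.1% in the weaker part, a difference of 18.0 percentage points. That explanation is thus argued against as the whole cause, while easier chromatin recovery at open promoters was not tested, and no biological explanation was tested for this pattern.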
